A study of Mus musculus with 24 samples.

How the data were processed

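The series followed mouse hepatocytes from the embryo to the adult. It holds 24 samples. 18 are bulk polyA RNA-seq libraries of purified C57BL/6 hepatocytes, with 3 libraries at each of 6 stages: embryonic days 11.5 and 15.5 (E11.5, E15.5), postnatal days 1, 10 and 30 (P1, P10, P30) and 8 weeks of age (w8). 4 are single-cell libraries of dissociated liver, 1 each at E15.5, P1, P10 and w8. The last pair is a pooled activation screen, in which hepatocytes that carry a nuclease-dead Cas9 activator received guide RNAs directed at gene promoters; 1 library reads the transcriptome of each cell and the other the guides in it. Both name the G4 mESC line, a mouse embryonic stem cell line, as their source, per the labels, while the protocol text speaks of purified hepatocytes. Bulk libraries were made with a strand-marking KAPA kit and read as 75-base pairs, and single-cell libraries with the 10x Genomics 3' kit, per the labels' protocols. Cells of perfused or dissociated livers were washed at low speed and stained for Ceacam1, per the labels, whose text breaks off before the gate is described. The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries. Animals' sex is not given, but bulk libraries from E15.5 on read as male by Xist and Y-linked genes.

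For the bulk libraries the authors deposited whole-number read counts per gene; STAR, DESeq2 and R 4.2 with the mm39 build are named in the submitters' processing notes, which do not give the strand setting of the counting. Reads of antisense or overlapping genes, and of near-identical family members (Mup, Cyp2c, Cyp3a, Cyp4a, Saa, Ugt, Serpina1, Serpina3, haemoglobin and histocompatibility genes), are uncertain in that sense. The single-cell files hold deposited UMI (unique molecule) counts per gene and barcode, made with Cell Ranger 7.0.0 per the submitters' processing notes. The guide file holds deposited read and UMI counts of each guide in each listed cell barcode, with no further filter stated in the sources used here. Gene IDs were matched to symbols with a reference gene table of the GRCm38.p6 assembly; as the builds differ, no coordinates were used. Of 54446 IDs in the bulk table, 53229 matched with their version, 1180 without it and 37 did not; where IDs shared a symbol, the most deeply read one kept it and the other 102 were named by their ID. No column of values was left without a sample.

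Bulk totals were 19.4 to 70.9 M counts per library; CPM are counts scaled to the library size times its TMM factor. Replicates were compared pair by pair: their counts differed by a chi-square per degree of freedom of 9.58 to 274, so no library was a second copy of another. Genes were filtered with edgeR's filterByExpr on all 18 libraries, which left 16497, and tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, with TMM (trimmed mean of M values) factors and 1 fit over the 6 stages, since 3 libraries estimate a spread poorly. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold. Log2 fold changes are those of the fit, with a standard error (SE) taken as the change over the root of the test's F; levels are mean CPM ± SD with n = 3 unless stated. Where a stage held 0 counts, the fold is a lower bound against 3 counts over the stage's libraries; with 1 to 3 counts, it is the ratio of summed counts with a 95% counting interval. The interval of onset of a gene called higher at w8 than at E15.5 is the successive pair of stages with the largest rise of its mean log2 CPM (prior count 2). 34 gene lists, 20 of pathways or processes and 14 of cell type markers, were tested in each of 6 comparisons (204 tests) with limma 3.58.1's camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry; their adjusted p runs over the 204 tests.

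The genes that the text names follow a rule: the 10 called genes of largest change in each direction for w8 against E15.5 and the 5 for each successive pair, among genes of at least 20 CPM in the higher stage, leaving out predicted models and haemoglobin, immunoglobulin and Mup genes. Per list, these were up to 4 called members of largest change and up to 2 others of highest CPM. Afp, H19 and the targets of the screen are named in any case, and a few genes that the rule selects are not reported here. This rule, the lists, the tests, the thresholds and the alternatives were fixed before the data were examined, except where a choice is said to be later.

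Single cells were kept with at least 500 genes, at least 1000 UMIs and under 30% mitochondrial UMIs. Doublets were called with scrublet (scanpy 1.11.5, Python 3.11.15). Its automatic threshold marked 5.1% of cells at E15.5 but 0.0357% at P1, 0.0151% at P10 and 0% at w8; for those, chosen after seeing this, the highest scores were removed at 0.8% per 1000 barcodes (7.54%, 12.2% and 15.1%). No caller was run on the screen, so doublets remain in it; 2409 of its cells have no listed guide and the others a median of 2. Each library was clustered alone on 2000 variable genes, 30 principal components and 15 neighbours (Leiden, leidenalg 0.10.2, resolution 1). A cluster was named after a cell type ("hepatocyte-like") when at least 3 of that type's markers stood among its 50 genes of largest fold. A condition that a gene be seen in 25% of the cluster's cells, and a second naming round for genes of at least 500 CPM, were added after seeing the first names; shares of cells therefore rest on rebuilt names. With 1 library per stage no test between stages is possible: sums of UMIs have exact Poisson intervals and shares exact binomial (Clopper-Pearson) ones, at 95%, which cover counting error only.

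Zonation was read in hepatocyte-like cells thinned to 2000 UMIs and ordered along an axis of 5 pericentral genes (Cyp2e1, Cyp1a2, Oat, Cyp2c50, Gulo) and 5 periportal ones (Cyp2f2, Hal, Sds, Hsd17b13, Ass1). Cells were divided along the axis into 3 groups of equal size, and 50 held-out genes were compared between both outer groups; a gene was called zonated at 2-fold or more with at least 50 UMIs in the higher group. The axis itself is therefore not a result.

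In the screen, cell and guide pairs were used as listed. A cell counts for each guide listed in it, as a rule of 1 guide per cell left 3 guides with 20 cells. The guide is the unit: a guide's profile is its cells' summed UMIs as log2(CPM + 10), less the mean of all targeting guides with at least 20 cells. A target's own gene, and the mean of each of 11 lists, were set against all 7381 pairs of guides in an exact one-sided (own gene) or two-sided (list) permutation test, scaled for lists by the root of cell number; the smallest p is 0.00014. Lists were adjusted over 671 pairs of target and list. Similarity of same-target guides was tested with 100000 re-pairings, leaving out all 61 target genes, which is stricter than first laid down. A gene was counted as moved at 1.5-fold in both guides and at least 50 CPM, with 1000 random pairs of guides of different targets as background. Its fold is taken from means of log2(CPM + 10), so it differs from the ratio of the mean CPM printed beside it. The labels' amplicon text speaks of another, larger guide library, so the pairing of that text with these files was not used.

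Scripts were tested on simulated data. For w8 against E15.5, simulated over 15721 genes, 93% of 100 genes changed 3-fold and 97% of 100 changed 8-fold were called, with 1 false call. In the real comparison 48% of genes were called, so this simulation does not test library scaling under so broad a change. Simulated guides gave 31 of 31 targets raised 4-fold, 2 of 30 unraised targets, and 3 of 3 lists raised 1.5-fold with 0 of 241 others. Simulated adult cells gave 12 of 12 graded genes and 0 of 13 flat ones. Alternatives covered the tool (DESeq2 1.42.0), scaling, filters, fold minimum, libraries left out, cell filters, clustering, thinning, axis genes, pseudocount and cell minimum; numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were also used. Levels of the deposited transgene features were read only as a check of the libraries.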

Results

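The bulk series holds 18 libraries of purified mouse hepatocytes, 3 each at E11.5, E15.5, P1, P10, P30 and w8. Depth ran from 51.4 to 70.9 M counts per library at E11.5, 39.1 to 42.3 at E15.5, 28.7 to 41.1 at P1, 19.4 to 39.4 at P10, 32.2 to 45.4 at P30 and 30.5 to 33.8 at w8. The number of genes with a count fell from 24110 ± 120 at E11.5 to 17150 ± 424 at w8 (mean ± SD, n = 3). Albumin mRNA alone took 1.78% of counts at E11.5, 11.7% at E15.5, 10.2% at P1, 15.9% at P10, 12.7% at P30 and 7.2% at w8. The first principal component held 59.3% of the variance and the second 22.4%. Liver single-cell libraries, 1 per stage, had 8919 cells in use at E15.5 (median 19550 UMIs), 7767 at P1 (20540), 11593 at P10 (12750) and 9188 at w8 (4122). The screen library had 6761 cells (median 29820 UMIs), of which 4352 carried at least 1 guide against 61 targets or a non-targeting guide.

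How far does the adult hepatocyte's transcriptome stand from the fetal one? Between E15.5 and w8, 3186 of 16497 genes rose and 4729 fell by at least 2-fold. The median log2 fold change over all genes was -0.21 with TMM factors, -0.234 with RLE and -0.332 with upper-quartile ones, against -0.06 from the 6 libraries of both stages alone and -0.0514 for genes of at least 10 CPM in 3 libraries. Cyp2c29, a drug-oxidizing cytochrome P450, stood at 1480 ± 192 CPM against 0 counts (at least 69200-fold; edgeR quasi-likelihood adjusted p = 1.7e-07). Serpina3k, a plasma protease inhibitor, stood at 19300 ± 2910 against 0.0433 ± 0.0376 CPM (log2 fold change 18.7 ± 0.86 SE; quasi-likelihood adjusted p = 1.2e-11). The protease inhibitors of the macroglobulin family rose with it: Mug1 from 0.0144 to 4170 ± 528 CPM (292000-fold, 80800 to 2410000) and Mug2 from 0 counts to 844 ± 150 CPM (at least 39500-fold). Complement factor C6 (356 ± 46 CPM, at least 16500-fold), the fatty acid elongase Elovl3 (296 ± 118 CPM, at least 13900-fold) and the P450 Cyp2c54 (221 ± 39.7 CPM, at least 10200-fold) also came up from 0 counts. The acute-phase genes Saa1, Saa2 and Orm1 belong to the 10 largest rises. For Saa1 and Saa2, 1 adult library carries most of the w8 mean: Saa2 read 7680 CPM in w8 replicate 3 against 23.6 and 14.7 in the others. Orm1 was high in all w8 libraries, at 1020, 1220 and, in replicate 3, 3160 CPM. Without replicate 3 Saa2 averaged 19.1 ± 6.3 CPM, Saa1 67.3 ± 25 and Orm1 1120 ± 140 (n = 2), against 0, 0.0146 and 0.0142 CPM at E15.5. In the fit over 6 stages Saa2 had an edgeR quasi-likelihood adjusted p of 0.0053, and of 0.069 from the 6 libraries of both stages alone; without replicate 3 its bound is at least 901-fold.

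The imprinted growth-control RNA H19 fell from 16400 ± 1290 to 0.0254 ± 0.0221 CPM (641000-fold, 178000 to 5300000), the growth factor Igf2 from 628 ± 67.2 CPM to 0 counts (at least 16400-fold), and the Notch-related membrane protein Dlk1 from 3630 ± 118 to 0.0129 CPM (284000-fold, 51000 to 11200000). Afp, the fetal counterpart of albumin, fell from 69000 ± 1060 to 1.84 ± 0.117 CPM, a log2 fold change of -15.2 ± 0.5 (edgeR quasi-likelihood adjusted p = 2e-14). Gpc3, a surface proteoglycan of fetal liver and liver cancer, fell from 1500 ± 14.3 to 0.0129 CPM (118000-fold, 21100 to 4640000). The RNA-binding protein gene Igf2bp1 (102 ± 3.01 CPM, at least 2680-fold), the keratin Krt20 (143 ± 12, at least 3730-fold) and the adhesion receptor Igdcc4 (137 ± 9.71, at least 3580-fold) went to 0 counts. So did the amino acid carrier Slc36a2 (109 ± 5.25, at least 2840-fold) and the hypoxia factor Hif3a (100 ± 8.12, at least 2620-fold).

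Which processes carry these changes? All 22 drug-metabolizing P450 genes rose, and their summed level went from 990 ± 11.8 to 31900 ± 6440 CPM (camera adjusted p = 8.1e-23, and adjusted p = 0.0028 with an estimated correlation). Cyp2e1, which oxidizes ethanol and paracetamol, rose from 1.34 ± 0.342 to 6040 ± 648 CPM (log2 12.1 ± 0.3), Cyp2c50 from 0.0146 to 581 ± 65.8 CPM (40600-fold, 11200 to 335000), Cyp2c38 from 0 counts to 33.3 ± 0.0471 CPM (at least 1550-fold) and Cyp2f2 by a log2 of 8.44 ± 0.26. Bile acid synthesis and transport genes rose in 19 of 20 cases (camera adjusted p = 2e-19, and 0.014 with an estimated correlation). They were led by the hydroxylase Cyp7b1 (log2 12.4 ± 0.5, 410 ± 131 CPM at w8) and the transporter Slco1a1 (12.2 ± 0.44, 1100 ± 421 CPM). Slco1a4, another carrier, rose 5520-fold (1530 to 45600) and the reductase Akr1c6 by a log2 of 7.95 ± 0.33; Acox2 did not pass at 218 ± 26.6 against 249 ± 17.1 CPM. Of 20 fetal and oncofetal genes, 19 fell, and their sum went from 94300 ± 1510 to 8.87 ± 1.47 CPM (camera adjusted p = 4.1e-34, and 0.00046 with an estimated correlation). Of 30 periportal genes 25 rose and 1 fell (camera adjusted p = 3.3e-14, and 0.043 with an estimated correlation), among them the steroid enzyme Hsd17b6 (0.167 to 288 ± 121 CPM). Of 30 pericentral genes 19 rose and 4 fell (camera adjusted p = 5.4e-06; adjusted p = 0.24 with an estimated correlation), while the pericentral Rgn and Lect2 did not pass, at 1130 ± 227 against 628 and 77.3 ± 16.3 against 86.8 ± 4.46 CPM.

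Conjugation enzymes rose in 18 of 21 cases (camera adjusted p = 4.2e-15; adjusted p = 0.12 with an estimated correlation). The glucuronosyltransferases led: Ugt2a3 from 0.167 to 532 ± 146 CPM, the bilirubin-clearing Ugt1a1 from 0.0282 to 62.3 ± 7.93, Ugt2b1 from 7.56 to 1240 ± 390 and Ugt1a9 from 0.642 to 101 ± 18.2. Ugt2b34 (998 ± 199 against 811 ± 41.5 CPM) and Gstt1 (201 ± 39.6 against 232 ± 8.89) did not pass. Urea cycle and amino acid genes rose in 19 of 20 cases (camera adjusted p = 1.2e-09; adjusted p = 0.24 with an estimated correlation). The largest rises were those of the tryptophan oxygenase Tdo2 (0.0983 ± 0.066 to 2500 ± 752 CPM, log2 14.6 ± 0.92) and the tyrosine transaminase Tat (1540 ± 535 CPM at w8, log2 9.62 ± 0.58). Sds (log2 6.73 ± 0.7) and Prodh (6.25 ± 0.23) rose too, and Nags did not pass at 69.1 ± 7.03 against 57.2 ± 3.76 CPM. Of 16 gluconeogenic and glycogen genes 11 rose (camera adjusted p = 3.5e-05; adjusted p = 0.19 with an estimated correlation). G6pc rose from 0.193 to 448 ± 197 CPM, Pck1, its partner in glucose output, from 4.96 ± 0.243 to 3500 ± 882, and Fbp1 from 31.2 ± 10.3 to 1490 ± 190. The glycogen phosphorylase Pygl (683 ± 120 against 496 CPM) and the glucose carrier Slc2a2 (437 ± 81.8 against 264) did not reach 2-fold. Genes of glycolysis in proliferating cells fell in 7 of 16 cases (camera adjusted p = 0.0021; adjusted p = 0.29 with an estimated correlation). Among them were the hexokinase Hk2 (488-fold, 167 to 2370), the lactate exporter Slc16a3 (1350-fold, 242 to 53300), Hk1 (log2 -7.38 ± 0.54) and Pkm (log2 -5.35 ± 0.36). Ldha (1050 ± 265 against 1340 ± 75.3 CPM) and Gapdh (821 ± 50 against 1180 ± 41.1) did not pass.

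Fatty acid oxidation genes rose in 12 of 22 cases and 1 fell (camera adjusted p = 5.1e-05; adjusted p = 0.38 with an estimated correlation). The largest rises were those of Cyp4a10 (0.0657 to 228 ± 58 CPM), Cyp4a14 (0.277 to 157 ± 21.9), Acaa1b (21.6 to 604 ± 192) and Pex11a (6.59 to 112), known targets of the receptor PPAR-alpha. Acaa2 and Hadha did not pass at 1010 ± 178 against 644 and 519 ± 34.6 against 453 ± 34.1 CPM. Cholesterol synthesis had no common direction, with 2 of 20 genes higher and 5 lower (camera adjusted p = 0.72). The cyclase gene Lss fell by 2.45 ± 0.33 on the log2 scale, while Sc5d rose by 1.71 ± 0.14. Hmgcs1 did not pass the 2-fold minimum (533 ± 262 against 934 CPM) but passed without w8 replicate 3 (log2 -1.29). Of 30 plasma protein genes 12 rose and 2 fell (camera adjusted p = 0.0026; adjusted p = 0.54 with an estimated correlation). The lipoprotein genes Apoa4 (log2 9.63 ± 0.34) and Apoc3 (8.43 ± 0.38), the haemoglobin scavenger Hp (4.66 ± 0.5, lifted by w8 replicate 3) and Fetub (4.55 ± 0.14) rose, and Alb (88100 ± 10100 against 104000 ± 2990 CPM) and Ahsg (8600 ± 638 against 11400 ± 537) did not pass. Complement genes rose in 13 of 20 cases and 1 fell (camera adjusted p = 6.3e-07; adjusted p = 0.24 with an estimated correlation), with the lectin Mbl2 (log2 5.94 ± 0.22), C4bp (5.78 ± 0.15) and C9 (5 ± 0.31) in front. C3 (12200 ± 7560 against 6670 ± 446 CPM) and Cfi (1230 against 1020) did not pass, though C3 passed without w8 replicate 1 or 2 (log2 1.06 and 1.16).

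All 28 mitotic genes fell (camera adjusted p = 2e-11; adjusted p = 0.29 with an estimated correlation). The proliferation marker Mki67 fell from 349 ± 29.7 to 1.28 ± 1.57 CPM, the topoisomerase Top2a from 222 ± 11.9 to 1.27 ± 1.48, and so did Kif23 (log2 -8.82 ± 0.72) and Bub1 (log2 -7.37 ± 0.56). Of 32 hepatocyte transcription factors 18 rose (camera adjusted p = 8.8e-05; adjusted p = 0.24 with an estimated correlation): the bile-acid-induced repressor Nr0b2 (0.795 to 18.9 ± 7.74 CPM), Nfix (6.18 to 121 ± 30) and the xenobiotic sensor Nr1i3 (0.572 ± 0.0602 to 10.3 ± 2.18). Hnf4a (906 ± 73.4 against 516 ± 3.04 CPM) and Xbp1 (267 ± 45 against 246) did not pass 2-fold. Clock genes rose in 10 of 19 cases and 4 fell (camera adjusted p = 0.081): Nr1d1 (1.11 to 99 ± 31.9 CPM), Bhlhe41, Dbp (0.995 to 37.7 ± 20) and Nr1d2 (5.87 to 158 ± 61.1) rose. Hlf (61.8 ± 13.4 against 70.1 CPM) and Bhlhe40 did not pass, the latter passing without w8 replicate 1 (log2 1.2). The hour of sampling is not stated. All 14 male-biased genes rose (camera adjusted p = 7.7e-11, and 0.018 with an estimated correlation), such as the urinary protein Mup20 (0.0222 to 4150 ± 1730 CPM; 192000-fold, 65700 to 931000) and Cyp4a12b (0 counts to 98.4 ± 1.06 CPM, at least 4580-fold). Female-biased genes went both ways, 3 of 17 higher and 6 lower (camera adjusted p = 0.14): Prom1 (log2 -9.36 ± 0.25) and Hao2 (log2 -9.08 ± 0.38) fell, Sult2a1 fell 333-fold (59.6 to 13200), A1bg rose at least 19.6-fold (not without w8 replicate 3), and Abcd2 and Cyp3a44 did not pass. Dissociation and stress genes rose in 8 of 20 cases and 1 fell (camera adjusted p = 0.26). Among them were the heat-shock genes Hspa1b (0.454 to 19.1 ± 11.2 CPM), Hspb1 (0.653 to 20.8 ± 10.6) and Hspa1a (log2 2.71 ± 0.99), and the phosphatase Dusp1 (2.88 ± 0.54), with Jun and Junb not passing. Hspa1a lost its call without w8 replicate 1 or 2, or E15.5 replicate 1 or 3, and Junb gained one without w8 replicate 1 (log2 1.12). Counts of calls adjusted over the list alone were the same as over all genes tested for every list of this pair of stages but Kupffer cell and endothelial markers.

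**Figure D1:**
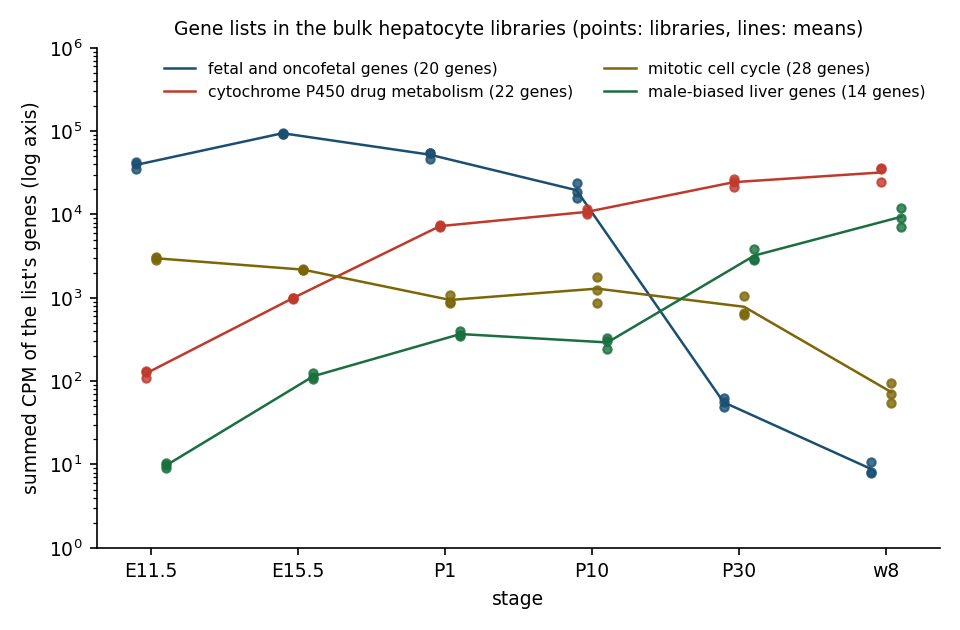
Summed CPM of fetal, P450, mitotic and male-biased genes in each bulk library, on a log axis. Points are libraries and lines are stage means.

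How pure are the sorted cells? Markers of other cell types were low and moved with stage. Stellate markers summed to 1700 ± 154 CPM at E11.5, 900 ± 118 at E15.5 and 15.2 ± 5.4 at w8. From E15.5 to w8, 11 of 18 were lower and 1 higher (camera adjusted p = 0.0094; adjusted p = 0.57 with an estimated correlation), such as Col1a1 (151 ± 28.9 to 0.0254 CPM) and Col3a1 (log2 -10.1 ± 1.1). Mesothelial markers, with Upk3b and Msln, fell in 8 of 8 cases (camera adjusted p = 0.019; adjusted p = 0.43 with an estimated correlation) and neutrophil markers in 10 of 13 (0.018; adjusted p = 0.54 with an estimated correlation), Mpo from 16.9 CPM to 0 counts. Endothelial markers had 8 of 16 lower and 3 higher, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.27); the scavenger receptor Stab1 fell from 34.8 to 0.653 CPM and Gpr182 from 38.9 ± 2.45 to 0.49, while Fcgr2b rose. Kupffer cell markers had 3 higher and 5 lower of 16, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.94): Clec4f rose from 0.0841 to 0.934 CPM and Lyz2 fell from 9.17 to 0.484. Erythroid markers fell in 13 of 18 cases and 3 rose (camera adjusted p = 0.1), Hbb-bs from 94.5 ± 14.4 CPM to 0 counts; haemoglobin took 0.0201% of E15.5 counts. In the order megakaryocyte, monocyte, mast cell, stem cell, B cell and T or NK cell, 8 of 9, 7 of 9, 5 of 5, 7 of 10, 7 of 10 and 3 of 4 markers fell (camera adjusted p = 0.16, 0.42, 0.36, 0.061, 0.61 and 0.47), Ppbp, Ccr2, Tpsb2, Kit, Pax5 and Klrb1c among them. Of the same lists 2 monocyte markers and 1 B cell marker rose. Cholangiocyte markers had 2 higher and 4 lower of 10 (camera adjusted p = 0.88), and Clu, also a hepatocyte product, rose from 193 ± 17.2 to 2010 ± 694 CPM while Krt19 fell by 4.82 on the log2 scale. Hepatocyte markers themselves rose in 12 of 22 cases and 1 fell (camera adjusted p = 6.2e-05; adjusted p = 0.19 with an estimated correlation). Of 5 sex-chromosome genes the Y-borne Eif2s3y and Uty rose by 1.16 ± 0.39 and 1.05 ± 0.39 on the log2 scale and Ddx3y did not pass at 104 ± 16.1 against 58.6 ± 4.5 CPM (camera adjusted p = 0.72). The call of Eif2s3y ended without w8 replicate 2, and that of Uty without w8 replicate 1 or 2 or E15.5 replicate 1 or 2 and with upper-quartile factors.

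Sex genes separate the first stage from the rest. The X-inactivation RNA Xist read 60.4, 214 and 105 CPM in the E11.5 libraries, beside Ddx3y at 32.4, 4.99 and 32.1. At E15.5 Xist was at 0.0206 to 0.204 CPM with Ddx3y at 54.5 to 63.5, and in later libraries Xist stayed at or below 0.0831 with Ddx3y at 53 to 121. The step from E11.5 to E15.5 therefore differs in these genes as well as in age. E11.5 also has TMM factors of 1.79 to 1.86 and a lower mitochondrial share (1.25% of counts against 4.38% at E15.5 and 7.49% at P1). By Xist and Ddx3y the bulk libraries from E15.5 on read as male. Changes of male-biased and female-biased genes after E15.5 are therefore those of males, and the course in females was not measured.

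What does the fetal step from E11.5 to E15.5 bring? From E11.5 to E15.5, 3131 genes rose and 1939 fell. The P450 Cyp3a11 rose to 63 ± 3.21 from 0.00525 CPM (10300-fold, 2860 to 85400), Fbp1 to 31.2 ± 10.3 CPM (10200-fold, 1820 to 402000). The lipid-mobilizing factor Azgp1 rose from 0.0134 to 61.7 ± 4.77 CPM (log2 12 ± 0.27), Cfhr2 from 0.0411 to 62 ± 7.22 and the sulfotransferase Sult1a1 from 0.135 to 105 ± 4.43. Lin28a, which blocks let-7 microRNA, fell from 65.7 ± 8.88 to 1.06 ± 0.317 CPM, Sox11 from 29.3 ± 1.4 to 0.358, Onecut3 from 40.5 ± 6.63 to 0.0291 and Tmeff1 from 26.8 ± 4.47 to 0.723; Xist fell from 127 ± 79.1 to 0.103. The edgeR quasi-likelihood adjusted p was 1.2e-12 for Cyp3a11, 1e-15 for Azgp1, 4.9e-10 for Lin28a and 2.6e-10 for Sox11. In this step hepatocyte markers rose in 21 of 22 cases (camera adjusted p = 4.2e-26, and 0.00046 with an estimated correlation) and plasma protein genes in 29 of 30 (1.3e-29, and 0.014 with an estimated correlation). Conjugation enzymes rose in 19 of 21 cases, or 20 adjusted over the list alone (camera adjusted p = 3.3e-24, and 0.031 with an estimated correlation), P450 genes in 16 of 22 (2.4e-17, and 0.0041) and bile acid genes in 17 of 20 with 1 lower (9.6e-25, and 0.0028). Gluconeogenic genes rose in 14 of 16 (camera adjusted p = 3.8e-10, and 0.029 with an estimated correlation), complement genes in 16 of 20 (1.9e-23, and 0.014) and periportal genes in 25 of 30 with 1 lower (2.1e-18, and 0.021). Glycolytic genes fell in 8 cases and 1 rose (camera adjusted p = 0.0012; adjusted p = 0.29 with an estimated correlation), and the fetal list had 3 higher and 5 lower (camera adjusted p = 0.49). Beside these rises, stellate markers summed to 1700 ± 154 CPM at E11.5 and 900 ± 118 at E15.5, and hepatocyte markers to 44200 ± 6820 and 227000 ± 2090. Neutrophil markers rose in 12 of 13 cases (camera adjusted p = 4e-05; adjusted p = 0.29 with an estimated correlation) and so did endothelial ones in 14 of 16 (0.011; adjusted p = 0.61 with an estimated correlation).

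What changes around birth? From E15.5 to P1, 3108 genes rose and 1393 fell. Cyp4a14, an omega-hydroxylase of fatty acids, rose from 0.277 ± 0.179 to 1940 ± 539 CPM (log2 12.8 ± 0.48; edgeR quasi-likelihood adjusted p = 4.4e-12), Cyp4a10 from 0.0657 to 562 ± 182, Apoa4 from 0.0586 to 307 ± 64.9 and Serpina3k from 0.0433 to 246 ± 201. The angiogenic Prok1 reached 34.6 ± 18.7 CPM (4960-fold, 890 to 196000). Serpina6, which carries corticosteroids in plasma, fell from 6590 ± 243 to 22.2 ± 4.72 CPM (log2 -8.22 ± 0.3), Dlk1 from 3630 ± 118 to 42.6 ± 8.11. The coactivator Cited1 fell from 85.5 ± 6.88 to 0.802, the imprinted Rtl1 from 27.2 to 0.379 and the hexokinase Hkdc1 from 76.6 ± 4.27 to 1.78. Fatty acid oxidation genes rose in 15 of 22 cases (camera adjusted p = 7.6e-11; adjusted p = 0.19 with an estimated correlation), and their sum went from 4640 ± 407 to 16700 ± 1740 CPM. Cholesterol synthesis fell in 16 of 20 (camera adjusted p = 7.3e-07; adjusted p = 0.38 with an estimated correlation), from 6420 ± 152 to 2560 ± 317 CPM, and mitotic genes fell in 24 of 28 (0.00015; adjusted p = 0.57 with an estimated correlation). P450 genes rose in 19 of 22 cases (camera adjusted p = 9.8e-24, and 0.0028 with an estimated correlation) and bile acid genes in 17 of 20 (3.1e-17, and 0.014), while the fetal list fell in 12 cases and 2 rose (camera adjusted p = 3.2e-08, and 0.031 with an estimated correlation). Markers of other cells were higher at P1: endothelial markers summed to 1290 ± 161 CPM (98.7 ± 6.02 at E15.5; camera adjusted p = 7.8e-11; adjusted p = 0.24 with an estimated correlation). Neutrophil markers summed to 1120 ± 298 (92.7 ± 24.7, camera adjusted p = 0.00011, and adjusted p = 0.29 with an estimated correlation). Kupffer cell markers summed to 612 ± 170 (161 ± 7.77, camera adjusted p = 8.4e-06, and adjusted p = 0.36 with an estimated correlation). Most of that E15.5 sum of 161 CPM was the gene Slc40a1, with 20292 counts over the 3 libraries.

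What changes while the pups are suckling? From P1 to P10, 1180 genes rose and 2943 fell. The organic anion carrier Slc22a7 rose from 0.332 to 113 ± 8.23 CPM, Tdo2 from 8.08 ± 8.68 to 669 ± 165, and C9 from 2.93 ± 0.339 to 178 ± 80.5 (edgeR quasi-likelihood adjusted p = 1.3e-12 for Slc22a7 and 1e-06 for Tdo2). Ntrk2 rose from 0.184 to 64.2 ± 34.9 CPM and the histocompatibility gene H2-Q1 from 0.325 to 25.9 ± 4.57. Of the 5 largest falls 4 were genes known from neutrophil granules or cytoplasm: Ltf from 168 ± 45.8 to 1.24 ± 0.153 CPM, Olfm4 from 33.8 ± 9.53 to 0.116, Stfa1 from 92.2 ± 24.3 to 0.546 and Stfa2l1 from 30 ± 9.3 to 0.0627. Ggt1, a glutathione hydrolase of fetal hepatocytes, fell from 38.2 ± 3.66 to 0.0674 CPM. Neutrophil markers fell in 12 of 13 cases (camera adjusted p = 4e-10; adjusted p = 0.12 with an estimated correlation), endothelial ones in 16 of 16 (1.3e-09; adjusted p = 0.24 with an estimated correlation) and Kupffer cell markers in 15 of 16 (3.5e-05; adjusted p = 0.38 with an estimated correlation). The fetal list fell in 12 of 20 cases (camera adjusted p = 2.7e-10, and 0.013 with an estimated correlation). Urea cycle and amino acid genes rose in 10 of 20 (camera adjusted p = 7.6e-07; adjusted p = 0.32 with an estimated correlation), conjugation enzymes in 9 of 21 (1.1e-10; adjusted p = 0.19 with an estimated correlation). Complement genes rose in 8 of 20 with 2 lower (camera adjusted p = 1.5e-07; adjusted p = 0.24 with an estimated correlation).

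What comes with weaning? From P10 to P30, 1147 genes rose and 2336 fell. The male-biased hydroxylase Cyp4a12a rose from 0 counts to 115 ± 45.5 CPM (at least 2710-fold), Cyp4a12b to 20 ± 6.91 (at least 475-fold), and Elovl3 to 115 ± 38.4 (at least 2720-fold). The carboxylesterase Ces3b rose from 0.401 ± 0.313 to 585 ± 74.9 (log2 10.7 ± 0.41; edgeR quasi-likelihood adjusted p = 7.6e-11) and Ugt2b37 to 28.8 ± 3.38 (1080-fold, 297 to 8880). H19 fell from 14300 ± 1790 to 9.8 ± 4.77 CPM (log2 -10.5 ± 0.34), Igf2 from 418 ± 34.2 to 0.00923 (38400-fold, 6900 to 1520000). The perinatal P450 Cyp3a16 fell from 349 ± 105 to 0.0725, Krt20 from 40.3 ± 17.1 CPM to 0 counts (at least 1170-fold) and Tenm4 from 36.8 ± 2.71 to 0.0342 (1160-fold, 396 to 5630). Afp stood at 3610 CPM at P10 and 3.75 at P30. The fetal list fell in 17 of 20 cases (camera adjusted p = 2e-40, and 0.00032 with an estimated correlation), from 19500 ± 4130 to 55.9 ± 7.07 CPM. In the same step stellate markers fell in 12 of 18 cases (306 ± 29 to 51.3 ± 15.7 CPM; camera adjusted p = 0.0003; adjusted p = 0.41 with an estimated correlation) and endothelial ones in 15 of 16 (125 ± 51.1 to 23.4 ± 7.14; camera adjusted p = 1.6e-05; adjusted p = 0.4 with an estimated correlation). Kupffer cell markers summed to 395 ± 34.3 and 161 CPM. At w8 most of their sum of 175 CPM was the gene Slc40a1 (13298 counts over 3 libraries). The adult sum is therefore not a measure of macrophage RNA as a whole. Male-biased genes rose in 13 of 14 (camera adjusted p = 3.7e-24, and 0.0026 with an estimated correlation) and P450 genes in 15 of 22 (3.3e-13, and 0.014 with an estimated correlation). Cholesterol synthesis came back in 18 of 20 genes (camera adjusted p = 2e-11; adjusted p = 0.24 with an estimated correlation), to 5980 ± 175 CPM. Female-biased genes fell in 12 of 17 cases and 4 rose (camera adjusted p = 7e-06; adjusted p = 0.054 with an estimated correlation).

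What is left after P30? From P30 to w8, 243 genes rose and 920 fell, or 149 and 519 from the 6 libraries of both stages alone. Mki67 fell from 96.8 ± 39.6 to 1.28 ± 1.57 CPM (log2 -6.21 ± 0.6; edgeR quasi-likelihood adjusted p = 6.4e-06) and the kinetochore motor Cenpe from 20.3 ± 10.4 to 0.26, within a fall of 27 of 28 mitotic genes (camera adjusted p = 6.1e-59, and 0.014 with an estimated correlation). Female-biased genes fell in 13 of 17 cases (camera adjusted p = 1.1e-20, and 0.0028 with an estimated correlation), with Hao2 (36.5 ± 4.08 to 0.088 CPM) and Cyp2b9 (40.1 ± 15.9 to 0.529) among the largest. Male-biased genes rose further in 8 of 14 (camera adjusted p = 3.3e-08, and 0.024 with an estimated correlation) and the fetal list fell in 8 of 20 (1e-09, and 0.021 with an estimated correlation). The circadian factor Dbp rose from 2.76 ± 2.69 to 37.7 ± 20 CPM, and Cyp7b1 from 48.4 ± 16.8 to 410 ± 131. Hspb1 rose from 2.43 ± 0.675 to 20.8 ± 10.6, Tiam2 from 3.44 ± 1.09 to 25.7 ± 6.18, and Saa3 from 3.4 ± 1.28 to 27.8 ± 32.8 (8.89 ± 0.45 without w8 replicate 3, n = 2). Of 204 list tests, 112 were called at the preset correlation and 24 held with an estimated one. Those were the fetal list in every step but the first and in the whole span, and P450 genes in the span, the first, the second and the fourth step. Bile acid genes held in the span and the first and second steps, periportal genes in the span and the first step, and male-biased genes in the span and the last 2 steps. Conjugation, gluconeogenic, plasma protein, complement and hepatocyte genes held in the first step, and mitotic and female-biased genes in the last.

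When do adult genes come up? Of the 3186 genes higher at w8 than at E15.5, 1321 (41.5%) had their largest rise by P1, 801 (25.1%) by P10, 900 (28.2%) by P30 and 164 (5.15%) by w8; 1083 were called in no single interval. Fatty acid oxidation and bile acid genes were perinatal, with 11 of 12 and 14 of 19 in the interval to P1. Urea cycle and amino acid genes had 12 of 19 in the interval to P10, Tdo2 among them. Male-biased genes had 11 of 14 in the interval to P30. P450 genes split, with 14, 2, 6 and 0 genes in the 4 intervals: Cyp2e1 was at 1830 ± 187 CPM by P1, but Cyp2c29 at 1.35 at P1, 45.6 at P10 and 1250 at P30. Conjugation enzymes were spread as 7, 6, 5 and 0, complement genes as 4, 6, 3 and 0, and clock genes as 4, 1, 1 and 4. By the first interval in which a gene is called, the counts were 1284, 387, 397 and 35. These counts describe kinetics and carry no test.

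**Figure D2:**
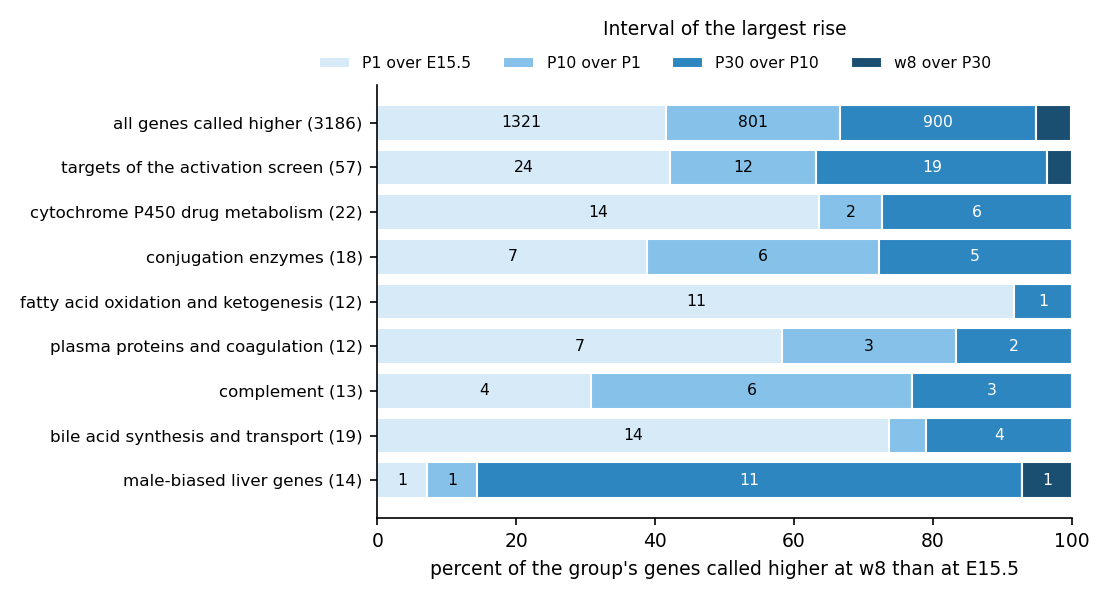
Interval of largest rise of genes called higher at w8 than at E15.5, as a percentage of each group of genes.

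How do the 61 genes targeted in the screen behave in the time course? 57 of them rose from E15.5 to w8 (57 also adjusted over the list alone). The study chose these genes on these samples, so their direction is not independent evidence. Klf9, a glucocorticoid- and thyroid-responsive factor, rose from 1.35 ± 0.409 to 164 ± 12.8 CPM (log2 6.92 ± 0.28; edgeR quasi-likelihood adjusted p = 1.2e-12), Hopx from 0.349 to 49.1 ± 9.67, and Atoh8 from 0.142 to 18.8. Zbtb16 rose by a log2 of 5.8 ± 0.83, Irf7 by 5.19 ± 0.24 and the muscle protein gene Csrp3 to 27.6 ± 9.69 from 0.00755 ± 0.0131 CPM. Onset differed: Klf9 was at 61.4 CPM by P1, Prkaa2, a catalytic subunit of the energy sensor AMPK (5.67 to 143 ± 24.9), rose by P10, Bcl6 (3.06 to 47.3) and Creg1 (49.3 to 640 ± 161) by P30, and Dbp and Zfp809 last. Over the 4 intervals the onsets were 24, 12, 19 and 2 of 57. Esr1, the estrogen receptor, stood at 3.85 CPM at E15.5, 89.9 at P10 and 47.8 ± 29.8 at w8. Cebpa rose little, from 280 ± 6.68 to 573 ± 96.8 CPM (log2 1.03 ± 0.14), and Pparg rose from 0.433 to 9.37 CPM. Atf5, Chd9, Prox1 and Xbp1 were not called; Prox1 read 132 ± 73.7 against 168 ± 4.8 CPM. Step by step 17, 36, 18, 28 and 5 targets rose; 1 fell in the first step, 4 in the third, 3 in the fourth and 1 in the last, or 3 in the last adjusted over the list alone.

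Which cells make up the dissociated liver at each stage? Hepatocyte-like cells made up 21.5% of cells at E15.5 (20.6 to 22.3), 27.8% at P1 (26.8 to 28.8), 42.8% at P10 (41.9 to 43.7) and 57.9% at w8 (56.9 to 58.9). There is 1 library per stage, so no stage difference is tested and the intervals cover counting error only. Cells without a name were 29.2% at E15.5 (median 36629 UMIs), 14.3% at P1 (5316), 9.32% at P10 (4647) and 36.2% at w8 (1230). Erythroid cells were 27.6% of the fetal liver (26.6 to 28.5), 8.02% at P1, 3.38% at P10 and no cluster carried that name at w8, where rare cells inside other clusters would not be seen. Neutrophils were at 6.25%, 16%, 4.71% and 1.03%, the peak at P1 being at the stage with the highest neutrophil markers in the sorted bulk cells. Kupffer cells were at 5.12%, 9.58%, 13.7% and 1.43%, endothelial cells at 0.673%, 5.86%, 6.01% and 0.697%, and stellate cells at 0.706%, 2.79%, 7.57% and 1.83%. B cells were at 0.863%, 7.22% and 6.12% up to P10, stem cells at 3.43% at E15.5, and megakaryocytes at 1.79% at E15.5 and 0.399% at P1. The E15.5 single-cell library also carries UMIs of the screen's activator transgenes, at 3.17 CPM for dCas9 (2.94 to 3.41), against 0 UMIs in the other liver libraries.

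Do the single-cell and bulk time courses move the same genes? Log2 ratios of summed hepatocyte-like cells and bulk fold changes had a Pearson correlation of 0.841 across 11947 genes for w8 against E15.5 (Spearman 0.819), with the same sign in 91.2% of 5174 called genes; the E15.5 library is the one with transgene UMIs. For P1 against E15.5 it was 0.795 across 12680 genes and for P10 against P1 0.59 across 13446. Afp went from 30518 CPM (30469 to 30567) in fetal to 12755 at P1, 1163 at P10 and 72.1 in adult hepatocyte-like cells, Cyp2e1 from 0.708 (0.49 to 0.989) to 1066, 2236 and 1655, and Tdo2 from 0 to 13, 347 and 1660. Nr1i3 was at 4.27, 106, 89.8 and 42.4 CPM and Alb at 28417, 40829, 63764 and 30628, highest at P10, as in bulk at 196000. The fetal list summed to 48106, 26256, 9973 and 693 CPM, and 215 adult cells in 2 clusters hold most of that last value: without them it is 98.8, and Afp is at 6.17. Fatty acid oxidation genes summed to 3112, 9408, 7250 and 5703 CPM highest at P1 as in bulk, and cholesterol synthesis to 4419, 1140, 1341 and 2434. P450 genes summed to 479, 5097, 6321 and 12917 CPM, and male-biased ones to 47.9, 262, 140 and 11885. Adult haemoglobin genes read 1769 CPM in fetal hepatocyte-like cells, 234 at P1, 21.2 at P10 and 2.03 at w8, a measure of RNA from other cells in these sums. Stress genes stood at 444, 474, 434 and 1440 CPM.

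**Figure D3:**
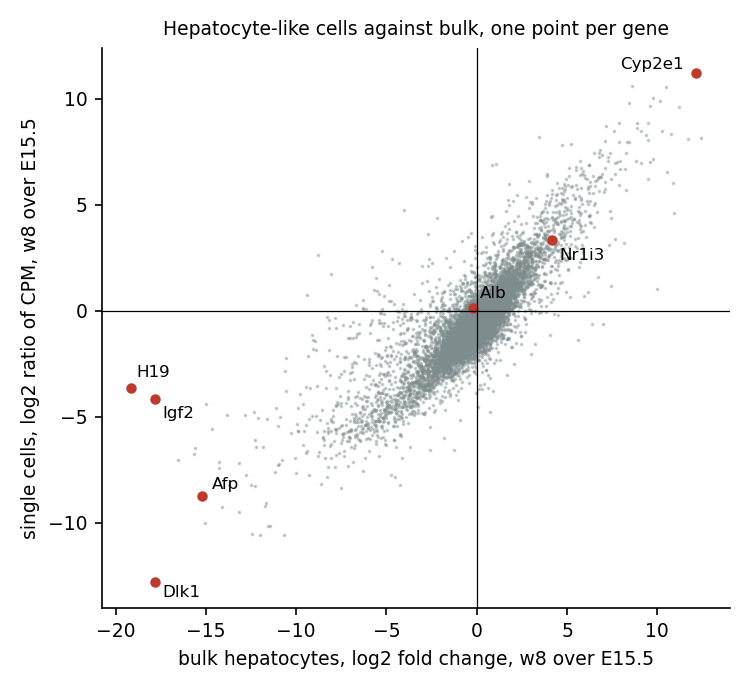
Log2 ratio of hepatocyte-like cells against bulk log2 fold change for w8 over E15.5, 1 point per gene. Bulk values are fitted ones, so genes with 0 to 3 counts at a stage are not bounds here.

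When does zonation of the lobule appear? Of 50 held-out genes, 1 was zonated on its listed side at E15.5, 6 at P1, 18 at P10 and 22 at w8, with 1319, 1792, 4524 and 4335 cells ordered; the E15.5 library is the one with transgene UMIs. With the other axis genes the counts were 1, 0, 19 and 9, so neither the calls at P1 nor the rise from P10 to w8 hold under that choice. Cells thinned to 4000 UMIs gave 7 at E15.5, while 1000 UMIs or 2 groups of cells gave 0, so the 1 call there depends on these settings. At P1 the count was 2 with 1000 UMIs, 1 with 2 groups of cells and 2 under 15% mitochondrial UMIs. Glul, the glutamine synthetase of the innermost pericentral layer, gave 119 UMIs on the pericentral and 132 on the periportal side at E15.5, then 414 and 185 at P1 (2.24-fold), 1869 and 290 at P10 (6.44-fold) and 1466 and 116 at w8 (12.6-fold; 92.7% pericentral, 91.3 to 93.9). The glutamate carrier Slc1a2 went from 130 and 20 UMIs at P10 (6.5-fold) to 336 and 24 at w8 (14-fold), and the Wnt co-receptor gene Lgr5 from 3.74-fold to 11.8-fold. Cyp2c29 had 147 and 102 UMIs at P10 and 3778 and 280 at w8 (13.5-fold). Lect2, a Wnt target, was pericentral at every stage (2.02-fold at E15.5, 66.9% of UMIs with an interval of 61.2 to 72.3, 3.28-fold at P1, 2.3-fold at P10, 10.7-fold at w8). Cyp2c37 was so from P1 (2.14-fold) to w8 (390 and 34 UMIs), and Cyp2a5 (10.3-fold), Cyp2c54 (8.84-fold), the transcription factor Tbx3 (8.38-fold) and Rgn (6.59-fold) at w8. Nr1i3 was itself pericentral at w8, with 203 and 43 UMIs (4.72-fold). On the periportal side the glutaminase Gls2 (2.8-fold at P1, 3.47-fold at P10, 2.63-fold at w8) and Etnppl (2.48-fold, 3.81-fold, 2.17-fold) came first, and Hsd17b6 (3.04-fold) and Spp1 (3.6-fold) were called at P10. Ctsc (4.4-fold), the cadherin Cdh1 (3.64-fold) and Apoa4 (2.4-fold) were periportal at w8, and the arginase gene Arg1 at P10 but not at w8 (1292 and 435 UMIs, 2.97-fold). Rhbg, an ammonia carrier, had 126 and 11 UMIs at P10. Aldh1a1 was on the opposite side at P10 (25 and 55 UMIs) and pericentral at w8 (2.36-fold). At E15.5 the axis itself rests on 1.77 UMIs per cell against 13.3 at w8, and 33 of 50 genes had too few UMIs there, so an absence of zonation before birth is not shown.

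**Figure D4:**
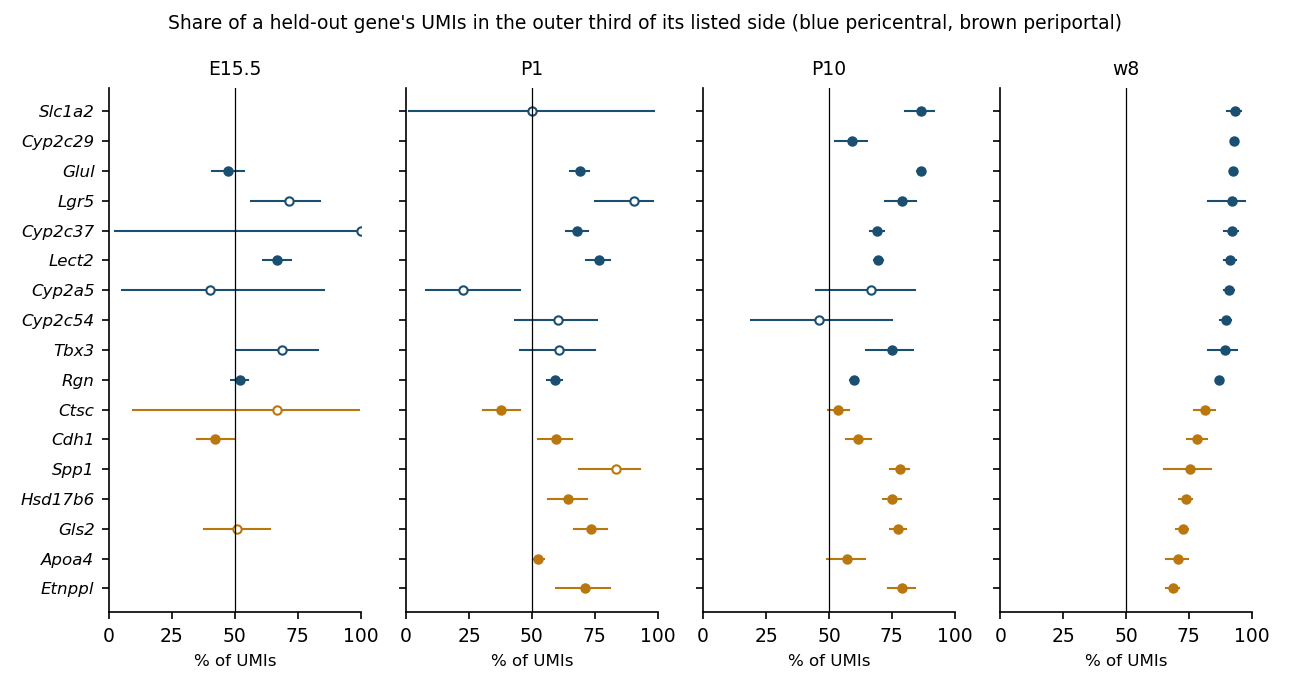
Percentage of a held-out gene's UMIs found in the outer group of cells on its listed side, with exact binomial intervals, at 4 stages. Open circles mark genes with under 50 UMIs in the higher group.

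Did the guides of the screen raise their targets? The guide file lists 15593 pairs of cell and guide, a median of 2 guides per cell and of 125 cells per guide (46 to 223). In an exact permutation test over guides, 57 of 61 targets passed on the mean level of their own gene over their 2 guides. A strong guide can carry that mean alone. For Ube2q2 (38.7 against 40.3 CPM) and Lpin1 (65.4 against 72.9), 1 guide was below the median of other guides. The same held for Rbl2 (18.5 against 22.7), Zfp809 (20.8 against 22.7) and Zfp874a (13.2 against 14.3). Ube2q2, Lpin1, Rbl2, Zhx2, Zhx3 and Xbp1 passed without both guides standing above both non-targeting guides. Nr1i3 read 524 and 367 CPM against 56.4 with other guides and 6.14 and 1.5 in non-targeting cells (log2 difference 2.8; exact permutation p = 0.00014, adjusted p = 0.00027). Esr1 read 1402 and 727 CPM against 153, the Notch effector Hes6 371 and 237 against 52, Parp14 349 and 762 against 109, the glucocorticoid-induced Tsc22d3 130 and 291 against 37.6, and Nr0b2 912 and 525 against 154. The adipogenic receptor Pparg read 880 and 389 CPM against 131, Irf5 98.8 and 48.4 against 10.3, Hspa1a 777 and 598 against 166 and Atoh8 78 and 172 against 23. Cebpa, which is already expressed, read 337 and 413 CPM against 120, and Csrp3 121 and 98.5 against 1.6. Crebrf (71.3 and 68.2 against 75.5 CPM; exact permutation, adjusted p = 0.89), Bcl6 (32.3 and 23.8 against 27.9; adjusted p = 0.5), Parp6 (6.79 and 10.5 against 8.11; adjusted p = 0.36) and Prox1 (158 and 172 against 146; adjusted p = 0.069) did not pass. Xbp1 passed with 163 and 168 against 151 CPM (exact permutation, adjusted p = 0.038) but non-targeting cells were at 167 and 169. Creg1 read 10814 CPM with 1 guide and 2007 with the other, against 1998. Non-targeting cells were below the other targeting guides for Esr1 (11.8 and 8.64 CPM), Nr0b2 (12.6 and 9.58) and Cebpa (44.8 and 49.6), and of cells with a guide 33.5% carry a single one.

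**Figure D5:**
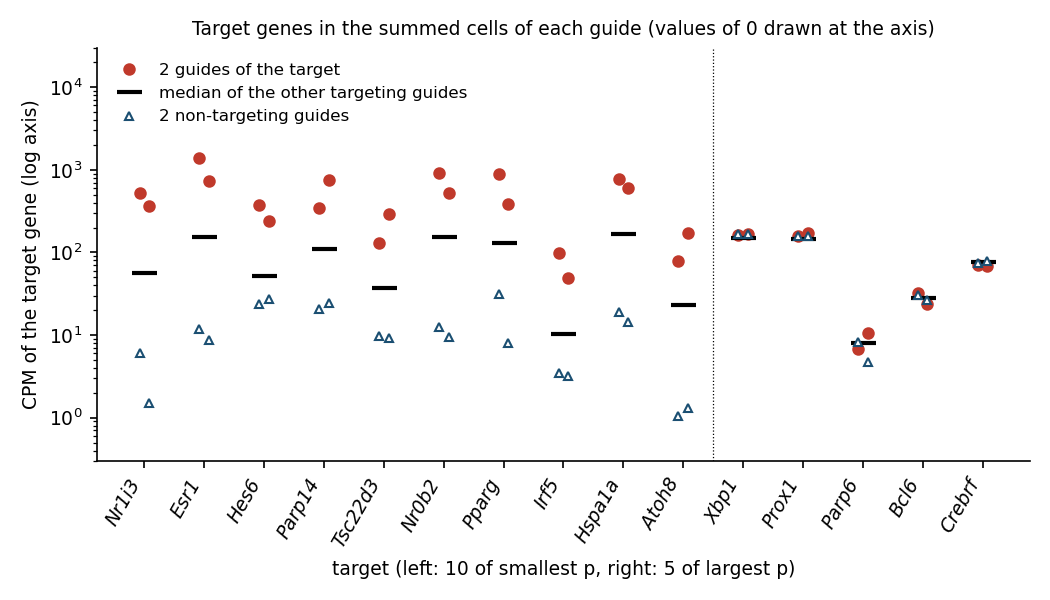
Level of the target gene with its 2 guides (red), with other targeting guides (bar, median) and with 2 non-targeting guides (triangles), for the 10 targets of smallest and the 5 of largest p.

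Do both guides of a target act alike? Their profiles correlated by 0.0628 on average over 3072 genes, against -0.00704 over re-pairings (permutation p = 1e-05, the smallest possible with 100000). The similarity is carried by few targets: 13 of 61 exceeded 0.187, the 95th percentile of guides of different targets, led by Cebpa (0.728) and Nr1i3 (0.704).

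Which targets move fetal or metabolic programmes? Of 671 pairs of target and list, 4 passed. Nr1i3, the constitutive androstane receptor, raised P450 genes 1.93-fold (score 0.95, guides 1.09 and 0.813; exact permutation p = 0.00014, adjusted p = 0.023), pericentral genes 1.88-fold (0.912) and conjugation enzymes 1.35-fold (0.438). The P450 and pericentral lists share genes such as Cyp2c29, Cyp2c50 and Cyp2c54, so these readouts are not separate evidence; a target is left out of its own list score. Pparg raised fatty acid oxidation 1.27-fold (0.34, guides 0.428 and 0.252; exact permutation, adjusted p = 0.023). Cebpa on periportal genes (0.176) had an exact permutation adjusted p of 0.055 and did not pass, but passed with pairs of at least 3 UMIs, where 7 readouts pass in place of 4, and with a pseudocount of 1 CPM (exact permutation, adjusted p = 0.018 in both; 0.018 to 0.97 over all alternatives). With 1 guide per target 0 readouts passed, a test of single guides having a larger smallest p. Downward scores did not pass either: Parp14 on urea cycle genes (-0.26; exact permutation, adjusted p = 0.11), Pparg on plasma proteins (-0.155; 0.11), Nr0b2, a repressor of bile acid synthesis, on bile acid genes (-0.194; 0.12), Parp14 on periportal genes (-0.169; 0.12) and Nfix on cholesterol synthesis (-0.186; 0.13). For the fetal list the smallest p was that of Nfix (-0.183; exact permutation p = 0.0068, adjusted p = 0.28), and for the mitotic list that of Pparg (0.596; exact permutation p = 0.0049, adjusted p = 0.23).

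Beyond the lists, 11 of 61 targets had more moved genes than the 95th percentile of random pairs (5 genes) and 2 exceeded their maximum of 18: Cebpa with 34 and Nr1i3 with 25. The count of 11 was 7 against non-targeting guides, 5 at 2-fold, 7 for genes of 200 CPM or more and 2 to 4 with single guides. Lpin1 and Nr0b2 followed with 10 each, Parp14 and Pparg with 9, Nfix with 8 and Dbp, Esr1, Id3 and Macrod1 with 6. Cebpa, a founding factor of the hepatocyte, raised Orm1 3.55-fold (776 and 786 against 228 CPM), the cortisone reductase Hsd11b1 3.15-fold (179 and 200 against 56), Wfdc2 3.12-fold and the male-biased Cyp4a12a 2.97-fold (159 and 189 against 54.1), and lowered Mt3 2.95-fold (60.2 and 56.6 against 212). Nr1i3 raised Cyp2c29 10.6-fold (2166 and 1340 against 202 CPM), its classical target Cyp2b10 7.05-fold (2664 and 1545 against 317), the glutathione transferase Gstm3 6.87-fold, Cyp2c55 5.71-fold and Pcp4l1 5.48-fold. The guides against Lpin1, a phosphatidate phosphatase, read 254 and 65.4 CPM of Lpin1 itself, against 72.9 with other guides. With these guides, lower levels were counted of Cyp2c29 5.6-fold (68.3 and 0.66 against 202 CPM), Pcp4l1 4.24-fold, Gstm3 2.39-fold, Cyp2b10 2.06-fold and Cyp2c55 1.74-fold. This is against the mean of targeting guides only: in non-targeting cells Cyp2b10 read 23.9 and 5.26 CPM (140 and 122 with Lpin1 guides), Pcp4l1 6.14 and 1.13 (12.2 and 17.8), Gstm3 89.7 and 85.4 (96.1 and 64.7), Cyp2c55 20.4 and 16.5 (29 and 24.4) and Cyp2c29 3.69 and 4.32. Those genes lead 1 cluster of cells in which Nr1i3 guides are frequent, and the profiles of the Lpin1 guides correlate by 0.148. These counts are set against a background and have no p of their own.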

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

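The tests of screen reads, of barcodes from another library, of mixed droplets and of cells with an Nr1i3 UMI were chosen after the results they measure had been seen; the others in this part were written down first. A signal in features that no comparison uses is the first pattern: UMIs of the screen's activator in the E15.5 liver single-cell library, 700 of dCas9 (3.17 CPM, 2.94 to 3.41; 6.66% of 9398 cells) and 179 of MS2-p65-HSF1 (0.81 CPM, 0.695 to 0.937; 1.88% of cells), each at 0 in the P1, P10 and w8 libraries (limits 0.0145, 0.0129 and 0.0316 CPM for dCas9).

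Reads of the screen library would bring its guide vector as well, but 0 of 402 expected UMIs of that vector were found, which argues against them. Transgenic cells confined to some clusters stay open: 0 of 19 clusters with at least 5 expected UMIs lacked dCas9, but RNA from broken cells can put UMIs in any cluster, and levels differed, with 0.786 and 1.1 CPM in 2 erythroid clusters among these 19 and, outside them, 15.1 CPM in stellate and 21.6 in endothelial cells. Xist and Y-linked genes summed to 2.49 CPM in the E15.5 library and to 2.49 in the screen (238, 266 and 212 at P1, P10 and w8), which is consistent with an embryo made from, or shared with, the line used for the screen (G4 mESC, per its label), as a hypothesis. Pooling with a sizeable share of other embryos would raise that sum in the E15.5 library. Males would add Y-linked genes, whose sum with Xist was 212 to 266 CPM in the later libraries. Females would add Xist, which read 60.4 to 214 CPM in the bulk E11.5 libraries. The sum of 2.49 CPM argues against such pooling, while a small share of other embryos stays open. Bulk E15.5 libraries, with Ddx3y at 54.5 to 63.5 CPM, are another source of cells.

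The second pattern is an adult cluster with fetal genes: 130 cells of the w8 library (median 25620 UMIs) with Afp at 1145 CPM, H19 at 6528 and Igf2 at 1691, against 9.18, 59.5 and 18.4 in other adult hepatocyte-like cells. Barcodes shared with another library numbered 0 of 130, which argues against stray reads in this cluster; the smaller one with fetal genes (85 cells), not part of this test, shared 9, or 10.6%. A droplet that mixes both cells cannot exceed the higher of them. Afp at 1145, H19 at 6528 and Igf2 at 1691 CPM stood against at most 60.4, 347 and 102 in any cluster that is not hepatocyte-like. The adult cluster was picked for high levels of fetal genes, which favours its place above other clusters. The gap therefore argues only weakly against mixed droplets. The count of fetal genes higher in a cluster that is not hepatocyte-like was 0 of 7 at 100 CPM or more, a set picked for high levels. It was 8 in a first form over all 20 genes with named types. Over 214 genes at least 4-fold higher in bulk at w8 than at P10, the cluster stood at a median log2 ratio of 0.366 to P10 cells (0.281 to 0.471), while other adult cells stood at 2.58. That interval comes from 10000 bootstrap resamples of the genes, so it covers the spread over genes and not counting error. Over 225 genes at least 4-fold lower at w8, the cluster stood at -0.0139 to P10 cells and other adult cells at -2.84. The cells may thus come from a P10 liver. Adult genes remained at a low level, however: Mup20 at 480 CPM against 9641 in other adult cells and 0 at P10. Cyp4a12a stood at 16.2 (294 and 0), Elovl3 at 7.94 (137 and 0), Cyp7b1 at 16.8 (266 and 3.92) and Hsd3b5 at 7.94 (153 and 0.464). The cluster held similar shares of these genes' UMIs in adult hepatocyte-like cells, from 0.291% for Mup20 to 0.368% for Cyp7b1. The source of this low level was not tested, nor was a biological explanation, such as rare immature adult cells.

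The third pattern is lower P450 and target genes in cells of the non-targeting guides, which were transduced separately: their P450 scores were -0.829 and -0.797, and 60 genes were lower and 11 higher with both guides. Random pairs of targeting guides moved a median of 2 genes, and 5 at the 95th percentile. Genes were counted by their mean level over targeting guides (at least 50 CPM). Genes high only in non-targeting cells could thus not enter, which tilts the counts toward lower ones. Leaving out 633 cells with an Nr1i3 UMI brought the score farther from 0 to -0.376, leaving out cells with an Nr1i3 guide to -0.612, and leaving out those and the cluster they led, the test laid down first, to -0.135. That set is chosen in part by the readout itself, so it was replaced, and cells activated through Nr1i3 may account for part of the gap. Cells with a non-targeting guide held a mean of 1.37 listed guides and other cells 3.76. Several guides in a cell were examined by the ratio of target genes to their non-targeting level. It was 1.17 times higher with 4 or more guides than with 1 (1.05 to 1.35), and stood at 1.35 with 1 listed guide. The interval comes from bootstrap resamples of the targets and covers the spread over targets only. Guides may be missed, as 2425 of 15593 pairs had 1 UMI, so cells with 1 listed guide may hold more. This test therefore cannot show how much of the gap several guides account for. Separate transduction is confounded with the guides, so for the score of -0.829 both cannot be told apart.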

How the results depend on the processing

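Alternatives with pairs of at least 3 UMIs, cells with at most 3 guides, unnamed clusters, fetal clusters or shared barcodes left out, and the E11.5 or P1 libraries left out were added after the results had been seen. Of 315 values for 33 main results, 252 stayed within their limits and 63 moved. No named gene or list that was called, and no passing score of the screen, changed its direction. For genes and lists that were not called, a change of direction was not recorded. With at least 10 CPM in 3 libraries, fewer genes were tested and the higher and lower counts were 1666 and 716 (E15.5 against E11.5), 1303 and 652 (P1), 564 and 1032 (P10), 607 and 1075 (P30), 109 and 601 (w8 against P30) and 1943 and 2255 (w8 against E15.5). With no fold minimum, more genes were called by construction: 5057 and 4744, 4817 and 4275, 4075 higher at P10, 3248 and 3836, 1333 and 2268, and 5340 higher for w8 against E15.5. From the 6 libraries of both stages alone, w8 against P30 gave 149 and 519; the cause was not tested. Leaving out 1 replicate at a time, higher counts were 2889 to 3260, 3040 to 3146, 1147 to 1244, 1053 to 1135, 191 to 291 and 3140 to 3274, and lower counts 1760 to 1978, 1282 to 1401, 2812 to 2954, 2031 to 2268, 689 to 1020 and 4588 to 4779, in the same order. Leaving out E11.5, P1 or both left each count within 1.5 times. By first called interval, which needs a call, onsets were 387 by P10, 397 by P30 and 35 by w8.

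List tests called fell from 112 to 24 with an estimated correlation; of 612 values for single lists under 3 alternatives 474 stayed, 90 were weaker and 48 stronger. With the replicate number as a block, 114 list tests were called, and 3117 genes rose from E11.5 to E15.5; the 14 counts stayed within 1.5 times. Libraries of equal number correlated by 0.000615 on average and 9 of 18 correlated best with their own number, so no pairing was assumed. Of 2282 values for named bulk genes 2260 stayed, 17 were weaker and 5 stronger.

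In the screen, 1 guide per target left 0 to 0 readouts (4 with both), as single guides give a larger smallest p, 2 to 4 targets with many moved genes (11 with both) and 43 to 50 raised targets (57 with both). Leaving out 1 bulk library at a time, 56 to 57 targets rose from E15.5 to w8. Readouts were 7 with pairs of at least 3 UMIs, Cebpa on periportal genes among them. Targets with many moved genes were 5 at 2-fold, 7 at 200 CPM or more and 7 against non-targeting guides. Same-target similarity was 0.0412 with pairs of at least 3 UMIs (permutation p = 0.0006) and 0.0651 with genes of 200 CPM or more (permutation p = 0.007). Rules of 1 guide per cell left 1153 and 243 cells, with 3 and 2 guides of 20 cells, and could not be run.

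Correlation of cells with bulk was 0.662 (P1 against E15.5), 0.457 (P10 against P1) and 0.63 (w8 against E15.5) over all cells, which takes in other cell types; under 15% mitochondrial UMIs it was 0.452 for P10 against P1 and 0.83 for w8 against E15.5, and 0.852 for the latter without the 2 adult clusters of fetal genes. Hepatocyte-like shares at under 15% mitochondrial UMIs were 19.5% (E15.5), 24.2% (P1), 44.1% (P10) and 81.1% (w8); with no such limit 23% (E15.5) and 45.8% (P10); with doublets kept 25.1% (E15.5), 33.5% (P10) and 56.4% (w8); at resolution 2 26.4% (P1), 40.8% (P10) and 62.2% (w8), and 47.2% (w8) at resolution 0.5. The adult share thus depends on the filter of mitochondrial UMIs. Over 29 shares of all cell types 69 of 149 values moved, so the other shares depend on these choices too. Zonated genes at E15.5 were 0 at 1000 UMIs, 7 at 4000 and 0 with 2 groups of cells. At P1 they were 2 at 1000 UMIs, 1 with 2 groups of cells, 0 with other axis genes and 2 under 15% mitochondrial UMIs. At w8 they were 9 with other axis genes (19 at P10, so that the order of both stages turned around), and 24, 21 and 26 without shared barcodes, without fetal clusters and with unnamed clusters. The causes were not tested. After thinning, 33 of 50 held-out genes at E15.5 and 9 at w8 had too few UMIs for a call.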

Other observations

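The cluster shares, the genes with a maximum between stages and the shared barcodes were chosen after the results had been seen, while the splits were planned. Guides of some targets gathered in clusters of the screen library. Cebpa guides had 45.7% of their cells in 1 cluster (40 to 51.5) that held 9.31% of all cells, with both guides near that share (44.8% and 50.8%). Nr1i3 guides had 46.4% in another (39.5 to 53.4, all cells 5.33%), with 53.8% and 36.5% for the single guides. Pparg, the receptor of fat storage, had 33% in a further one (28.3 to 37.9, all cells 7.72%), with 41.7% and 23.9%. The cluster of Nr1i3 held 0 of 289 cells with only non-targeting guides, 134 of 3815 with other targeting guides (3.51%) and 36 of 2409 with no listed guide (1.49%), and its marker Cyp2b10 stood at 2.09, 144 and 56.1 CPM in those cells and at 2142 with an Nr1i3 guide. The library also held macrophage-like (320 and 45 cells), mesothelial-like (167), stellate-like (91) and neutrophil-like (71) clusters beside hepatocytes.

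Some genes stood higher at P1 or P10 than at E15.5 and at w8. Sult2a1, a sulfotransferase of bile acids, stood at 4.24 CPM at E15.5, 103 at P1, 390 at P10, 2.47 at P30 and 0.0129 at w8, Cyp2b9 at 2.45, 88.5, 478, 40.1 and 0.529, and Cyp3a16 at 118, 474, 349, 0.0725 and 0.249. Female-biased genes as a list summed to 241 ± 7.47, 1170 ± 111, 2010 ± 72.7, 397 ± 117 and 80.8 ± 14.8 CPM (n = 3), while male-biased ones stood at 291 ± 45 at P10 and 9390 ± 2560 at w8. In hepatocyte-like cells female-biased genes summed to 148, 1398, 2069 and 151 CPM at E15.5, P1, P10 and w8. Without the 2 adult clusters of fetal genes the w8 sum was 42.6 CPM. Against E15.5, P10 had 2586 genes higher and 2629 lower.

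The P1 and w8 single-cell libraries share 925 barcodes, against 15 to 108 for other pairs of libraries. Shared barcodes had a median of 63783 UMIs at P1 and 650 at w8, and 145 of 9188 cells in use at w8 (37 of 5317 hepatocyte-like ones) are among them. They gathered in some clusters: 61 of 108 cells of an unnamed one (56.5%) and 18 of the 95 w8 neutrophils (18.9%). Their w8 profiles correlated by a median of 0.362 with their own P1 partner and of -0.00519 with other shared barcodes. Only 11.2% matched their own partner best, and the cause of the sharing was not tested. Acute-phase genes set w8 replicate 3 apart: Lcn2 averaged 2.24 ± 0.73 CPM without it and 128 ± 217 with it, Hp 3230 ± 170 and 6920 ± 6400.

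The 6 libraries of a pair of stages can be split in 10 ways, too few for a share under 0.05. In each of the 6 comparisons 1 split, the real one, gave as many genes as the real one. The other splits put libraries of both stages in each group, which adds the stage differences to the spread. Few calls could come from them in any case, so their counts are no measure of calls by chance. Real counts from those 6 libraries were 6818 (w8 against E15.5), 4780 (E15.5 against E11.5), 4197 (P1 against E15.5), 3611 (P10 against P1), 2550 (P30 against P10) and 668 (w8 against P30), and the highest of the other splits was 0 in each.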
